A study of Mus musculus with 15 samples.

How the data were processed

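Messenger RNA was measured in pools of 5 mouse embryos of the ICR strain, taken at the 2-cell stage 32 hours after insemination. Per the labels' protocols, mRNA was injected 2 hours after insemination, the lysed pools received ERCC spike-in RNA at a dilution of 1 to 40000, cDNA was amplified with 13 PCR cycles, libraries were made by Nextera XT tagmentation, and paired reads of 50 and 25 bases were taken. The submitters' processing notes name the mouse build mm10 and the programs Trimmomatic, Trim Galore, cutadapt, STAR and featureCounts, without versions. The gene annotation and the handling of strand are not given in the sources used here.

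The deposited table holds FPKM values (fragments scaled by gene length and by the assigned fragments of the library) made by the authors for 53023 genes in 6 libraries, with a length for each gene. It has 0 spike-in rows, so no scaling to spike-ins was made. The product of FPKM and length gives the number of reads in each gene up to 1 factor per library. With that factor, 100% of the values above 0 were multiples of 0.01 read (tolerance 0.0002 read), and between 55.58% and 57.88% were whole reads (tolerance 0.001 read), so reads shared between genes were counted as fractions. The recovered depth was 907210 to 1555431 assigned reads. In a gene of 2 kb, 1 read was worth 0.321 FPKM in the deepest library and 0.551 FPKM in the shallowest. Statements on depth and on a count of 0 (floor of 3 reads per library) cover counting error only, since PCR copies were not removed by molecular identifiers. Values of gene families with near-identical copies (Zscan4, Tdpoz, Usp17l, Obox, the actins) are uncertain for the single member. Of the gene identifiers, 99.8% are in GENCODE M21, and coordinates are those of the table.

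For these 6 libraries the titles and the annotation of the injected mRNA contradict each other, although both divide the libraries into the same 3 pairs. Pair A is titled Wt and annotated as non-injected. Pair B is titled R62D and annotated as injected with actinWT-HA-NLS. Pair C is titled as the non-injected control and annotated as injected with actinR62D-HA-NLS. Libraries are called A1, A2, B1, B2, C1 and C2 after the pair and the replicate number in the title. No library was moved between pairs, and no reading was chosen from the values. The other 9 libraries of the series, 3 each of Exportin 6 with R62D, G15S and a non-injected control, were not analysed here.

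Values were taken as log2(FPKM + 1), for the 13443 genes with a mean of at least 1 FPKM over the 6 libraries. A linear model with 1 mean per pair was fitted to all 6 libraries with limma 3.58.1 in R 4.3.3, with a variance trend, and p was adjusted over genes by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The labels do not say that the libraries of a pair came from separate matings or days, so p-values measure the spread between these pools. The method was tested on simulated data for C against B with 200 of 13443 genes changed, all drawn from genes above a minimum mean number of reads. With the spread seen between libraries it recovered 0% of genes changed 4-fold, 22.5% of those changed 8-fold and 42% of those changed 16-fold. At 8-fold it also called 22 unchanged genes, with a median of 0.5 reads. With counting error only, it recovered 40% of genes changed 4-fold. The variance shared across genes had less weight in the simulated fit (prior degrees of freedom 2.06 at 4-fold) than in the real fit (4.25). The recovered shares are therefore a rough guide only.

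Before the data were examined, 18 gene lists were fixed. The 13 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over 39 tests (13 lists in 3 comparisons), and again with a correlation estimated per list and with fry. The naming rule, also fixed then, took for each comparison up to 10 genes per direction that passed, or otherwise the 5 with the lowest unadjusted p among genes with a mean of at least 5 FPKM and pairs that did not overlap. It added Actb, Actg1 and Xpo6, and up to 4 members per list. After the values were seen, the list members named were narrowed to those of called lists, those with an unadjusted p below 0.05 and the muscle actins Acta1 and Actc1. Markers of other cell types, among them the globin genes, Ldhc and Odf2, are given as levels per library, and these genes were singled out after their values were seen. The 9 Y-linked genes and the test of X-linked genes were also chosen after the values were seen.

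The alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median scaling, quantile normalization, no variance trend, a fit of the compared pairs alone, the replicate number as a block, and leaving out each library. Added after seeing the data were limma-voom on the recovered reads, protein-coding genes only, and the list tests under these settings other than the replicate block, which was fixed beforehand for the lists as well. Where a library was left out, the 1 library left in its pair was assumed to vary like those of the other pairs. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.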

Results

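The study asked how the transcriptome of mouse 2-cell embryos responds when filamentous actin in the nucleus is disrupted. Its means was injection of mRNA for actin R62D, a mutant that does not polymerise, carrying an HA tag and a nuclear localisation signal. Wild-type nuclear actin and non-injected embryos were the controls. The 6 libraries analysed here form 3 pairs, A, B and C, of 2 pools each. The titles and the annotation disagree on what the pairs are. By the titles, A received wild-type actin, B received R62D and C was not injected. By the annotation, A was not injected, B received wild-type actin and C received R62D. Each comparison is given below by pair, with both readings.

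Assigned reads numbered 1000124 and 1117950 in A1 and A2, 1264831 and 1194638 in B1 and B2, and 1555431 and 907210 in C1 and C2. Libraries of the same pair correlated across genes at r = 0.896 (A), 0.91 (B) and 0.909 (C), within the range of 0.895 to 0.923 between libraries of different pairs. Principal component 1 held 28.7% of the variance and set A2 (score 49.3) and C2 (49.7) apart from the other libraries (-32.7 to -11.1). The same libraries had the lowest median level of 31 maternal and oocyte transcripts, -0.58 in A2 and -0.36 in C2 on the log2 scale relative to the mean of the 6 libraries. Mitochondrially encoded RNA took 13.13% of reads in A2 and 10.86% in C2, against 7.23% to 10.55% in the others. A2 and C2 also had the fewest genes at 1 FPKM or more, 12485 and 12279, against 13239 to 13845 in the others. The median level of 83 ribosomal protein genes was above 0 in A2 (0.28) and C2 (0.20) alone, and -0.21 to -0.02 in the other 4 libraries. Library B2 had 0 reads on 9 Y-linked genes, where a count of 0 of 1194638 allows up to 3 reads, while the others had 107 to 311 reads.

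**Figure D1:**
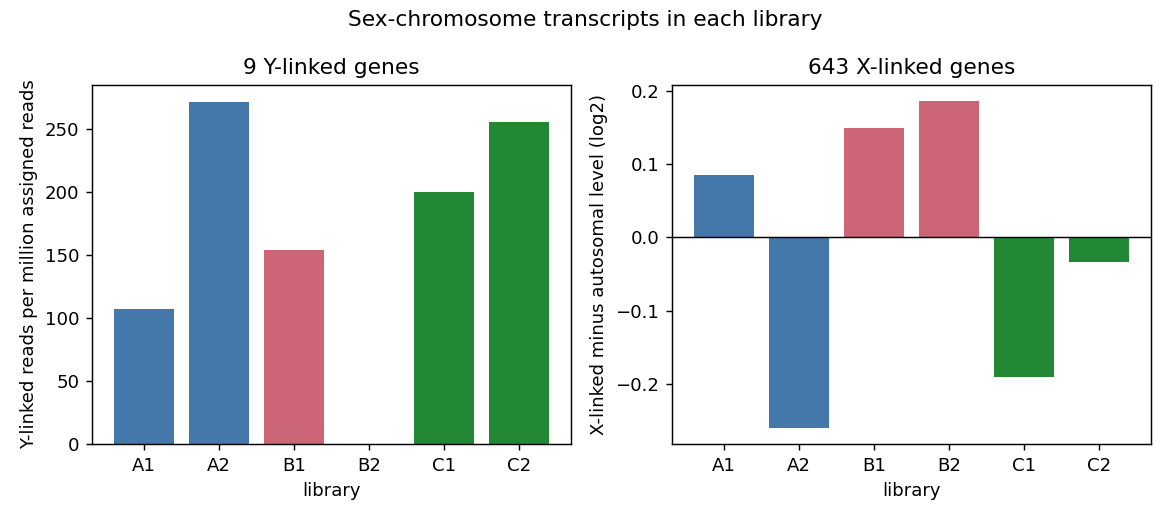
Left, rate of reads on 9 Y-linked genes among the assigned reads of each library, and right, the median level of 643 X-linked genes minus that of autosomal genes on the log2 scale, each gene taken relative to its mean over the 6 libraries. Bars are single libraries, coloured by pair. B2 has 0 Y-linked reads, and B1 (0.15) and B2 (0.19) have the highest X-linked levels.

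The actins were examined first, since the injected mRNA codes for actin. Actb, which encodes cytoplasmic beta-actin (chromosome 5, 142903115 to 142906754, mm10), was lowest in pair C. It measured 60.6 ± 12.2 FPKM in A, 95.1 ± 29.7 FPKM in B and 30.9 ± 5.33 FPKM in C (SD, n = 2). All 4 libraries of A and B lay above both libraries of C. The exact permutation p was 0.067 (one-sided), the smallest that the 15 splits of the libraries allow, for a contrast chosen after the values were seen. Over all genes no actin passed (limma, adjusted p = 1 for Actb in C against B and in C against A). Adjusted over the list alone, Actb, Acta1 and Actc1 were lower in C than in B, and Acta1 was lower in C than in A (limma). Acta1, skeletal muscle actin, and Actc1, cardiac actin, had 0 reads in both C libraries. In A they had 7 and 17.3 reads (Acta1) and 1 and 10.7 reads (Actc1), and in B 9.75 and 2.5 reads and 11.7 and 5 reads. The actins share coding sequence, so these reads cannot be assigned with certainty to 1 gene. Actg1, cytoplasmic gamma-actin, measured 8.65 ± 1.98, 8.13 ± 0.21 and 5.73 ± 3.57 FPKM in A, B and C (SD, n = 2). Xpo6, which encodes the nuclear exporter of actin, measured 2.31 ± 1.33, 1.89 ± 0.50 and 1.36 ± 0.82 FPKM in the same order.

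**Figure D2:**
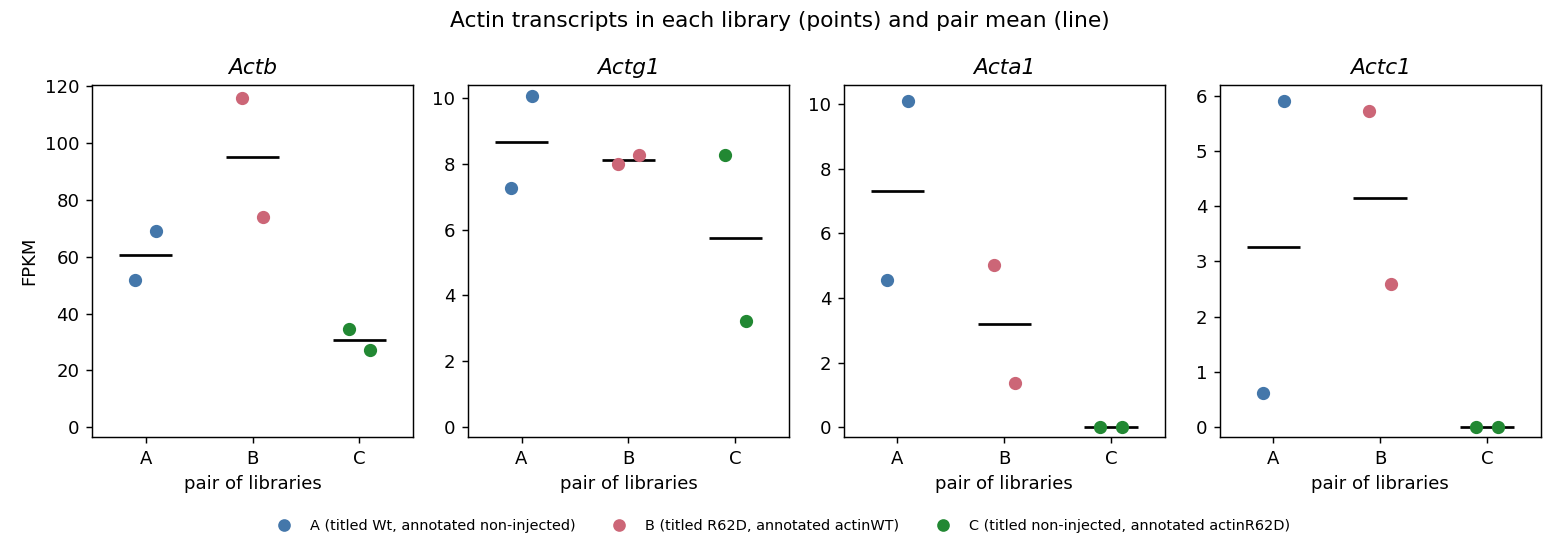
FPKM of Actb, Actg1, Acta1 and Actc1 in each library (points) with the mean of each pair (lines). Actb lies at 27.1 to 34.6 FPKM in pair C and at 52 to 116 FPKM in A and B, and Acta1 and Actc1 are listed at 0 in both C libraries.

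Pair C against pair B compares R62D with wild-type actin by the annotation, and non-injected embryos with R62D by the titles. Genes of the 2-cell-stage programme were lower in C, with 34 of 36 coefficients below 0 and a median log2 fold change of -0.55 (camera, adjusted p = 1.2e-05). The adjusted p was 0.99 with an estimated correlation. Here and below, such a loss cannot be put down to correlation alone. That test also raised p for p53 targets, whose estimate (-0.006) was below the preset 0.01. Their unadjusted p (camera) went from 0.26 to 0.312 in C against B and from 0.0978 to 0.173 in C against A. In B against A it went from 0.702 to 0.708. By library the pairs overlapped, since the median level of the list was 0.21 in C1 and -0.34 in C2 against 0.05 in B1 and 0.74 in B2. Zfp352, a zinc finger gene of the 2-cell stage, measured 146.5 ± 17.5 FPKM in C and 281 ± 56.2 FPKM in B (SD, n = 2), and Gm2016 and AA792892 had log2 fold changes of -1.14 ± 0.47 and -0.66 ± 0.28 (SE). The homeobox gene Obox5 went the other way, at 0.99 ± 0.38 (SE). Of 83 ribosomal protein genes, 70 had coefficients above 0, with a median of 0.20 (camera, adjusted p = 0.00196, and adjusted p = 0.99 with an estimated correlation). By library the median level of this list was -0.02 and 0.20 in C1 and C2 and -0.08 and -0.21 in B1 and B2, C2 being a library set apart on principal component 1. Rps15 measured 348.7 ± 57.2 FPKM in C and 196 ± 26 FPKM in B, and Rps26 254.9 ± 41.6 and 144.6 ± 15.6 FPKM (SD, n = 2). Without B2 neither list passed (adjusted p = 0.163 for 2-cell-stage genes and 0.154 for ribosomal proteins), and without C2 ribosomal proteins had an adjusted p of 0.933. B2 was also the library with 0 Y-linked reads.

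No single gene passed in C against B (limma, 0 higher and 0 lower of 13443, smallest adjusted p = 0.167). At an unadjusted p below 0.05 there were 220 higher and 298 lower genes, 518 in all where chance gives 672, and limma-voom on the recovered reads also called 0. The unadjusted counts became 205 higher and 537 lower without C1, and 185 higher and 177 lower without C2. Pairs did not overlap for 30.2% of genes, where chance gives 33.3%. Tktl1, an X-linked transketolase-like gene, measured 22.2 ± 0.55 FPKM in C and 78 ± 4.54 FPKM in B (SD, n = 2), a log2 fold change of -1.77 ± 0.30 (SE), with an adjusted p of 0.677 in limma. Npw, the precursor of neuropeptide W, measured 1.37 ± 0.51 FPKM in C and 18.3 ± 5.7 FPKM in B (SD, n = 2). The values of Fkbp2, a peptidyl-prolyl isomerase, were 23.6 ± 5.09 FPKM in C and 7.96 ± 0.55 FPKM in B. Gar1, a component of small nucleolar ribonucleoproteins, Tyms, thymidylate synthase, and the lincRNA AC134860.2 had log2 fold changes of 1.29 ± 0.34, 1.18 ± 0.33 and 1.33 ± 0.33 (SE). The pseudogene Igkv13-87 had 0 reads in both C libraries and 10 reads in each B library. The short RNA genes Mir7008, Mir878 and Snord47 rested on at most 2.83 reads in any library. Npw had 1 read in each C library, and Tpm4, given below, had 2.5 and 4 reads in C1 and C2. Fkbp2 had 7 and 6 reads in B1 and B2. Among list members, Mad2l1 of the spindle checkpoint, the p53 target Gadd45a, the germ cell helicase Ddx4, Rcl1 of ribosome biogenesis and the tropomyosin Tpm4 had log2 fold changes of 0.81 ± 0.29, 1.58 ± 0.58, 1.21 ± 0.48, 0.92 ± 0.37 and -1.37 ± 0.57 (SE), and none passed over its list alone. The lists of p53 targets (adjusted p = 0.596), SRF and MRTF targets (0.541), ribosome biogenesis (0.437) and chromatin modifiers (0.34) did not pass (camera), nor did DNA repair, nuclear actin transport, maternal transcripts, early lineage genes, heat shock and mitochondrial mRNAs (0.989 each), or cell cycle genes (0.988).

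Pair C against pair A compares R62D with non-injected embryos by the annotation, and non-injected embryos with wild-type actin by the titles. Cell cycle genes were higher in C, with 30 of 34 coefficients above 0 and a median log2 fold change of 0.37 (camera, adjusted p = 0.00379, and adjusted p = 0.99 with an estimated correlation). Plk1, a mitotic kinase, measured 23.2 ± 7.1 FPKM in C and 9.35 ± 1.01 FPKM in A (SD, n = 2). Rrm2, a subunit of ribonucleotide reductase, the proliferation marker Mki67 and the replication licensing gene Cdc6 had log2 fold changes of 0.54 ± 0.28, 0.60 ± 0.34 and 0.60 ± 0.35 (SE). All 13 mitochondrially encoded mRNAs had coefficients below 0, with a median of -0.36 (camera, adjusted p = 0.00196, and adjusted p = 0.99 with the estimated correlation of 0.877). By library the pairs overlapped, with median levels of -0.42 in C1 and 0.15 in C2 against 0.10 in A1 and 0.39 in A2. Examples were mt-Nd1 (-0.43 ± 0.28), mt-Co3 (-0.57 ± 0.37) and mt-Co2 (-0.46 ± 0.31, SE), while mt-Atp6 (-0.43 ± 0.30) went to 0 under quantile normalization. Without C1 neither list passed (adjusted p = 0.122 for the cell cycle and 0.893 for mitochondrial mRNAs), and mitochondrial mRNAs also failed without A2 (0.326) and after quantile normalization (0.635).

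In C against A 0 genes were higher and 0 lower (limma, smallest adjusted p = 0.344), and 0 by limma-voom. At an unadjusted p below 0.05 there were 225 higher and 180 lower, 55.6% higher, a share of 47.3% after median scaling and 46.8% after quantile normalization. Without A1 they became 366 higher and 194 lower, without C1 161 higher and 295 lower (35.3% higher), and without C2 322 higher and 152 lower (67.9% higher). Zfp42, a pluripotency gene, measured 18.4 ± 2.13 FPKM in C and 6.76 ± 0.53 FPKM in A (SD, n = 2), a log2 fold change of 1.32 ± 0.32 (SE). Fam136a, Gpha2 and Rwdd2a had log2 fold changes of 1.47 ± 0.32, 1.43 ± 0.33 and 1.41 ± 0.34 (SE). Marc1 measured 2.56 ± 0.84 FPKM in C and 9.5 ± 1.05 FPKM in A, and Tfb1m, a methyltransferase of mitochondrial ribosomal RNA, 2.41 ± 1.05 and 8.17 ± 0.36 FPKM (SD, n = 2). The receptor gene Kit had a log2 fold change of 1.10 ± 0.42 (SE). Igkv13-87 had 0 reads in both C libraries and 9 and 4 reads in A1 and A2. Mir7238, Snora47 and Snord16a rested on at most 3.5 reads in any library, and Gpha2 had 3 and 4 reads in A1 and A2. In C1 and C2, Marc1 had 11 and 4 reads and Tfb1m 6.5 and 2. The 2-cell-stage genes had a median of 0.14 (camera, adjusted p = 0.541), p53 targets 0.33 (adjusted p = 0.371), ribosome biogenesis 0.13 (adjusted p = 0.481) and maternal transcripts 0.14 (adjusted p = 0.879). The other 7 lists tested had an adjusted p of 0.989.

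Pair B against pair A compares wild-type actin with non-injected embryos by the annotation, and R62D with wild-type actin by the titles. The 2-cell-stage genes were higher in B, with 34 of 36 coefficients above 0 and a median log2 fold change of 0.62 (camera, adjusted p = 9.99e-07, and adjusted p = 0.99 with an estimated correlation). Zfp352 measured 281 ± 56.2 FPKM in B and 129.1 ± 25.3 FPKM in A, Zscan4d, of a telomere-linked gene family of this stage, 183.8 ± 43.4 and 81 ± 9.96 FPKM, and Tdpoz2 35.2 ± 3.72 and 13.6 ± 2.37 FPKM (SD, n = 2). Gm2016 had a log2 fold change of 1.45 ± 0.47 (SE). By library the median level of the list was -0.01 and -0.63 in A1 and A2 and 0.05 and 0.74 in B1 and B2. Gene by gene, B1 minus A1 had a median of 0.29 with 22 of 36 genes higher in B1, and B1 minus A2 a median of 0.81 with 32 of 36 higher. The adjusted p was 0.00858 without B2 and 0.0232 without A2. All 13 mitochondrially encoded mRNAs had coefficients below 0, with a median of -0.37 (camera, adjusted p = 0.00542, and adjusted p = 0.99 with the estimated correlation of 0.877). Among them were mt-Cytb (-0.47 ± 0.30), mt-Nd3 (-0.42 ± 0.25) and mt-Nd4l (-0.37 ± 0.26, SE), and mt-Atp6 (-0.42 ± 0.30) turned to 0.045 under quantile normalization. Of 83 ribosomal protein genes, 64 had coefficients below 0, with a median of -0.17 (camera, adjusted p = 0.00196, and adjusted p = 0.99 with an estimated correlation). By library the pairs overlapped, with median levels of -0.17 in A1 and 0.28 in A2, also set apart on principal component 1, against -0.08 in B1 and -0.21 in B2. Rps26, Rpl29, Rps15 and Rpl14 had log2 fold changes of -0.82 ± 0.29, -0.86 ± 0.36, -0.62 ± 0.28 and -0.60 ± 0.30 (SE). Mitochondrial mRNAs failed without A2 (adjusted p = 0.406), without B1 (0.257) and after quantile normalization (0.635), and ribosomal proteins failed without B2 (0.129) and turned in direction without A2 (0.82).

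**Figure D3:**
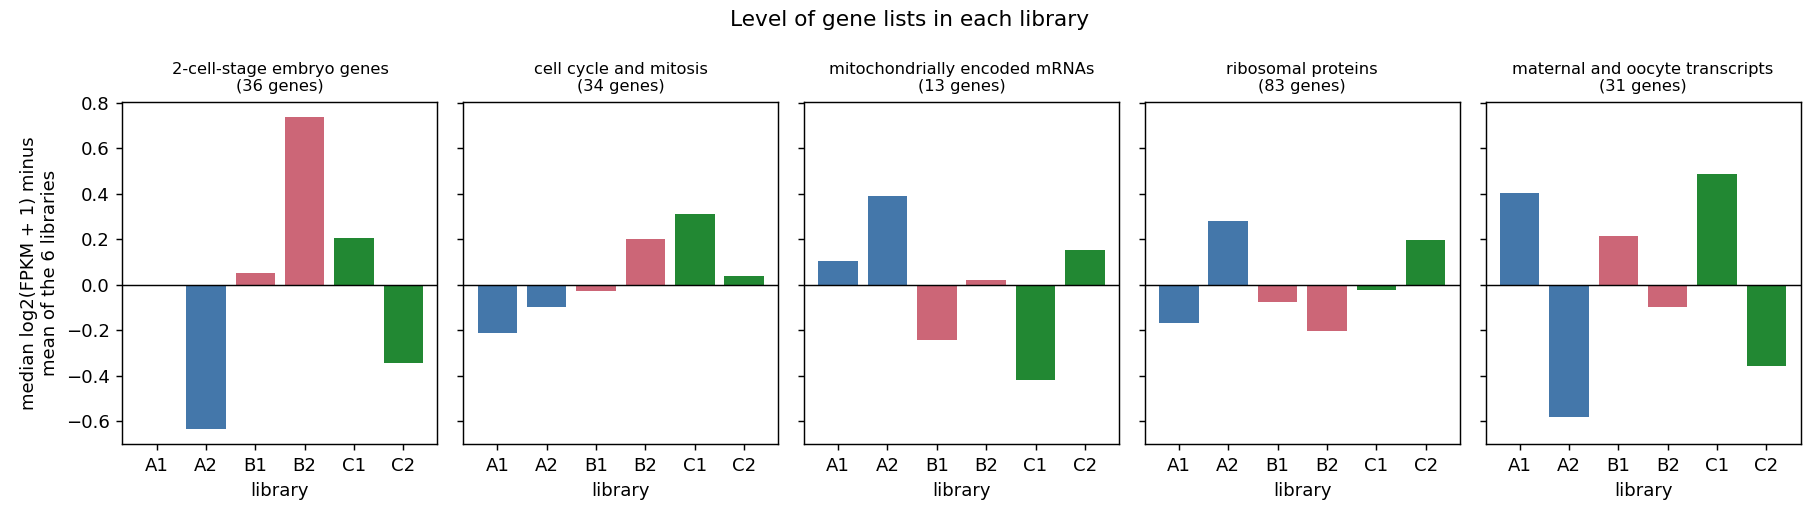
Median log2(FPKM + 1) of 5 gene lists in each library, relative to the mean of the 6 libraries, with bars coloured by pair. The 2-cell-stage list is highest in B2 (0.74) and lowest in A2 (-0.63), and A1 and B1 lie near 0.

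In B against A 0 genes were higher and 0 lower (limma, smallest adjusted p = 0.334), and 0 by limma-voom. At an unadjusted p below 0.05 there were 373 higher and 241 lower, 60.7% higher, a share of 53.3% after median scaling and 49.5% after quantile normalization. That share was 72.3% without A1 and 50.2% without A2. Zfp42 measured 21.1 ± 2.53 FPKM in B and 6.76 ± 0.53 FPKM in A (SD, n = 2), and was the 1 early lineage gene that passed adjusted over the list alone (limma, adjusted p = 0.0271). That list passed the fry test for change in either direction (adjusted p = 0.0118) and not camera (adjusted p = 0.989). Tmco5b measured 14.1 ± 0.83 FPKM in B and 1.17 ± 0.63 FPKM in A, and the noncoding AC121965.1 23.3 ± 1.44 and 4.56 ± 1.52 FPKM (SD, n = 2). Fkbp2, Tmem208, Bcdin3d and the pseudogene AC140477.1 had log2 fold changes of -1.64 ± 0.34, -1.36 ± 0.31, -1.74 ± 0.42 and -1.88 ± 0.42 (SE). Mir7008, Mir878, Snord35b and Mir1956 rested on at most 1.5 reads in any library. In A1 and A2, Tmco5b had 2 and 1 reads, and of genes given below Tpm4 had 1 and 6 and Tagln2 2 and 7. In B1 and B2, AC140477.1 had 2 and 1.5 reads, Bcdin3d 6 and 3, and Fkbp2 7 and 6. The deacetylase gene Hdac2, the germ cell gene Dazl, the SRF targets Tpm4 and Tagln2, and Gar1 had log2 fold changes of 0.96 ± 0.40, 1.16 ± 0.41, 1.40 ± 0.57, 1.29 ± 0.53 and -0.94 ± 0.34 (SE). The lists of cell cycle genes (adjusted p = 0.0632), chromatin modifiers and SRF and MRTF targets (0.371 each) and heat shock genes (0.879) did not pass (camera), nor did the other 5 besides early lineage genes (0.989 each). The cell cycle list passed as higher in B with no filter (adjusted p = 0.0295), with a filter at 5 FPKM (0.0403), with limma-voom (0.0123) and without B1 (0.0256), each at the preset correlation. In the main setting it had an adjusted p of 0.99 with an estimated correlation and 0.927 with fry.

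The 22 cumulus and granulosa cell markers together had 5 and 2 reads in A1 and A2, 12 and 26.5 in B1 and B2, and 23.5 and 5.5 in C1 and C2. Of them Tnfaip6 alone was tested, at 2.38 ± 0.10 FPKM in B, 0.26 ± 0.37 FPKM in A and 1.40 ± 0.15 FPKM in C (SD, n = 2). These values rested on 5 reads in each B library, 0 and 1 in A1 and A2, and 4 and 2 in C1 and C2. The 15 sperm and spermatid transcripts had 69.3 to 182 reads per library, most of them on Ldhc, a lactate dehydrogenase gene at 28.6 to 46 FPKM in all 6 libraries, and on Odf2 at 1.53 to 5.64 FPKM. Among 10 blood cell markers the alpha-globin gene Hba-a1 measured 42.3 and 8.81 FPKM in A1 and A2, 39.1 and 23.5 FPKM in B1 and B2, and 15.8 and 4.75 FPKM in C1 and C2, while the beta-globin genes Hbb-bt and Hbb-bs were listed at 0. Of 24 interferon and RNA sensing genes 4 were tested, and 0 had an unadjusted p below 0.05 in any comparison. Among lists that did not pass, the median was above 0 while camera gave the opposite direction for DNA repair, early lineage and heat shock genes in C against B, for chromatin modifiers, DNA repair, nuclear actin transport and ribosomal proteins in C against A, and for nuclear actin transport and ribosome biogenesis in B against A.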

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

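The settings added after seeing the data were limma-voom on recovered reads, protein-coding genes only, and the list tests other than those with an estimated correlation, fry and the replicate block. The counts of genes past the threshold were 0 in both directions of all 3 comparisons under every alternative run, leaving out each library included, except that a pseudocount of 0.1 gave 1 gene lower in C than in B, Igkv13-87 (adjusted p = 0.0342), which had 0 reads in C. The replicate number as a block also gave 0 genes and kept all 7 list calls. With the block, genes with an unadjusted p below 0.05 rose in each comparison and direction (limma). They were 286 higher and 385 lower in C against B, 273 and 224 in C against A, and 435 and 289 in B against A. Deviations of same-numbered libraries from their pair means correlated at 0.098, 0.203 and 0.005. The main fit did not take the numbers to pair the libraries, and such a pairing is not excluded. An estimated correlation (adjusted p = 0.99) and fry (0.927) each lost all 7 list calls. Estimates were 0.877 for mitochondrial mRNAs, 0.443 for ribosomal proteins, 0.346 for 2-cell-stage genes and 0.053 for the cell cycle, above the preset 0.01. The preset treated members as nearly independent, but the losses need not come from correlation alone. Quantile normalization ended both mitochondrial calls (0.635), and the cause was not tested. Leaving out 1 library gave adjusted p from 1.01e-07 to 0.163 for 2-cell-stage genes in C against B and 1.01e-07 to 0.0232 in B against A, 8.34e-06 to 0.933 for ribosomal proteins in C against B and 1.27e-08 to 0.82 in B against A (reversed without A2), 0.0025 to 0.122 for the cell cycle in C against A, and 1.04e-06 to 0.893 and 0.00135 to 0.406 for mitochondrial mRNAs in C against A and in B against A. The number of list calls then ran from 5 to 13, of which 4 to 7 were among the 7. Calls gained, all at the preset correlation, were the cell cycle in B against A (4 settings, adjusted p 0.0123 to 0.0403), the actins, tested then with at least 5 genes, as lower in C than in A (1.03e-05 to 0.0279) and than in B (0.00272 to 0.0473) with no filter and with some libraries left out, and, each with 1 library left out only, maternal transcripts in all 3 comparisons, 2-cell-stage genes and ribosomal proteins in C against A (the latter in both directions, lower without A1 or C2 and higher without A2), SRF and MRTF targets in C against B and B against A, and chromatin modifiers, mitochondrial mRNAs and ribosome biogenesis in C against B. Signs were followed for the 86 entries of named genes only. Genes named for the lowest p had pairs that did not overlap, so leaving out 1 library could not turn them. Among the 86, log2 fold changes that changed sign when 1 library was left out were Actg1 (-1.116 to 0.021 in C against B, -0.277 to 0.145 in B against A), Xpo6 (-0.686 to 0.036 in C against B, -0.568 to 0.272 in B against A, with 0.03 without B2) and Actc1 (-0.491 to 1.601 in B against A). That of mt-Atp6 went to 0 in C against A and to 0.045 in B against A under quantile normalization, which gives the same value to the same rank. The scaling to ERCC totals and the comparisons of the other 9 libraries were not run. With 907210 to 1555431 reads, 2 libraries per pair and the spread seen between libraries, changes of 4-fold were not recovered in simulated data for C against B (0%). With counting error only, 40% of them were recovered.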

Other observations

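All tests of explanations in this part were chosen after the results they bear on were seen.

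Actin transcripts were lowest in pair C, which bears on the contradictory labels. If the annotation holds and the injected actin mRNA is counted in the actin genes, Actb should be higher in C and in B than in A. In C it was lower (log2 fold change -0.95 ± 0.35 SE, unadjusted p = 0.0282 in limma, not passing after adjustment), which argues against that explanation. In B it was higher, the way the annotation has it (0.62 ± 0.35 SE, not passing after adjustment). These predictions take the embryos' own Actb to be equal in the 3 pairs. If the titles hold and the injected mRNA is counted, Actb should be lower in C than in A and B. It was, at -0.95 ± 0.35 against A and -1.57 ± 0.35 against B (log2 fold change, SE), neither passing after adjustment (limma). The muscle actins, which share coding sequence with Actb, should then have fewer reads in C. The 4 muscle actins had 6 reads in C where the rate of A and B gives 40.8 (26.3 without A2). That is above the bound of 3 reads set for that test. The titles do not strictly require this bound, since Actb had 144.25 and 65.83 reads in C1 and C2 that may be shared. In an exact permutation test of muscle actin reads C was lowest at p = 0.067 (one-sided), the smallest its 15 splits allow, so this stays open. A first version on Acta1 and Actc1 alone, picked because both were at 0 in C, gave 0 reads where 34.9 were due and met the bound, and the fixed list of 4 was used instead. An annotation that holds with lower SRF activity in C also cannot be told apart, since the median of 9 SRF and MRTF targets in C against A was 0.25 with members on both sides of 0.

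The 2-cell-stage list was higher in B than in A and C at the preset correlation, and did not pass with an estimated correlation (adjusted p = 0.99 in both comparisons). Without B2 it still passed against A (adjusted p = 0.00858, median 0.44, 30 of 36 genes above 0), but pair B is then the single library B1, which exceeded A1 by a median of 0.29 and A2 by 0.81, so 1 library cannot exclude that B2 carries the difference, and the explanations cannot be told apart. Against C it no longer passed without B2 (adjusted p = 0.163, median -0.28 against -0.55 with it), and the level of C1 (0.21) lay above that of B1 (0.05), which leaves that part open too. Reads shared within gene families may count a single change repeatedly, but with each family summed the list still passed at the preset correlation (camera, adjusted p = 0.00607 for B against A and adjusted p = 0.00255 for C against B), with 15 of 16 values in the same direction in each. The summed list was not tested with an estimated correlation, which was 0.346 for the 36 single genes. Summing removes reads shared within a family, not variation shared between families. Both comparisons also rest on the same pair B. What was injected stays open as an untested biological explanation, as does the stage of the pools, since A2 and C2 also had the lowest maternal transcripts. A2 and C2 also had the fewest genes at 1 FPKM or more (12485 and 12279). Stage therefore cannot be told apart from other differences between these libraries.

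Library B2 had 0 reads on 9 Y-linked genes, and X-linked genes were higher in B (median log2 fold change 0.30 against A and -0.27 for C against B; camera p = 0.000242 and 6.59e-06, and p = 0.226 and 0.159 with an estimated correlation). Without B2 the medians were 0.25 and -0.20 (camera p = 0.00778 and 0.00105 at the preset correlation), with B1 as the single library of B. Depth is argued against, since the lowest rate of the other libraries gives 128 Y-linked reads in B2, and a candidate explanation is the sex of the pooled embryos, where at equal sexes the chance of at least 1 pool of 5 females among 6 is 17.3% (3.12% for a given pool). Over the 6 libraries the X-linked level went with fewer Y-linked reads at Pearson's r = -0.801 (exact permutation p = 0.0556, two-sided) and Spearman's rho = -0.886 (exact permutation p = 0.0333), and at r = -0.576 without B2 and A2 (1 relation computed). Their p-values fall on either side of 0.05, so for the X-linked level sex and other differences between the pools cannot be told apart. The 0 Y-linked reads of B2 do not rest on this relation. They are what a pool without male embryos would give, where the lowest rate of the other libraries gives 128.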
